A study of Homo sapiens with 36 samples.

How the data were processed

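RNA of LoVo cells, an established human colorectal cancer line, was measured after treatment with a MEK inhibitor or with its solvent DMSO for 24 hours. MEK is the kinase that activates ERK in the MAPK pathway. Per the labels' protocols, 10 ng of total RNA per sample was reverse transcribed, amplified gene by gene as short amplicons (Ion AmpliSeq), ligated to barcodes and pooled, with 18 samples in each pool. The amplicon panel reports on the genes it has primers for, and the number of counts of a gene depends on how well its amplicon amplifies. Levels of different genes are therefore not compared, apart from counts of fibroblast markers, where this limit applies.

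The values used are whole-number counts per gene that the authors deposited, with no normalization. The genome build was hg19, per the submitters' processing notes. The aligner and the counting tool are not given in the sources used here. The matrix of the whole series held the same values as the single files in all 36 libraries. Of 20812 rows in each file, 10 belong to spike-in controls and held 0 counts in every library, which left 20802 genes. Gene names are those of the files. Of these, 18298 are current symbols, 1667 are older symbols and 837 matched neither. No coordinates were used. Amplicons that cannot tell apart members of near-identical families, such as histone genes, metallothioneins, HSPA1A and HSPA1B, or pseudogene copies of HNRNPA3, would share reads, and values of those genes are uncertain in that respect.

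The 36 libraries form 12 groups of 3: DMSO libraries of chip 1, DMSO libraries of chip 2 and 10 doses from 0.03 to 1000 nM. The labels name the chip for DMSO libraries and not for treated ones. The labels mention biological replicates without saying how the cultures were separated, so the p-values measure the spread between these samples, part of which may be technical. Total counts ran from 2972186 to 4751839 per library, with a median of 3952427. Counts are not corrected for molecules amplified more than once, so counting intervals and bounds cover counting error only.

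Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, which left 12102, libraries were scaled by TMM, and a robust quasi-likelihood model with 12 groups was fitted to all libraries, with 24 residual degrees of freedom. Each dose was tested against the DMSO libraries of either chip, the larger of both p-values was adjusted by Benjamini-Hochberg over all tested genes, and a gene was called when the adjusted value was below 0.05 and both fold changes had the same sign. The fold change printed is against the mean of both DMSO groups, with the larger of both standard errors. Differences between doses a factor of 10 apart, and between the DMSO chips, came from the same model. Counts scaled to a common library size (CPM) use the TMM library sizes, and log2 values for curves and medians use a prior count of 1.

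Gene lists were fixed before the data were examined: 32 lists, of which 30 had at least 3 tested members. The list of mitochondrially encoded genes was not analysed here, and fewer than 3 blood cell markers passed the filter. EPGN, PHGR1, MUC5AC, ASCL2, MAP1LC3B and HBA1 were not analysed here. Lists were tested with camera of limma 3.58.1, which compares a list with all other genes, at a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks only whether a list's genes move one way on balance. EC50 values came from a least squares fit per gene of log2 CPM on base + top × dose/(dose + EC50), with DMSO as dose 0, for genes called at 1000 nM with a fold of at least 2. A gene counted as well fitted when the standard error of log10 EC50 was below 0.2. Fits and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

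Genes named in the text follow a rule fixed before the data were examined. At 1000 nM it takes the 10 largest rises and falls among called genes with a mean of at least 5 CPM in the higher group and every treated library beyond every DMSO library, all members of the MAPK activity list, and up to 4 members of each called list, or 2 of each other list, by adjusted p. At every other dose with calls it takes the gene that rose most and the gene that fell most, and at the lowest dose with calls 5 of each. For each step between doses it takes 3 of each direction, likewise for the chips, and for EC50 the 3 lowest and 3 highest among well fitted genes. MAP2K1, MAP2K2, BRAF, MAPK3, ACTB and GAPDH were always included. Some genes that the rule takes are not reported here.

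The procedures were tested on simulated counts before use, with 11954 genes. For 1000 nM against DMSO, 20% of 50 genes changed by 0.5 on the log2 scale were recovered, 84% at 1, 100% at 2 and 100% at 3, with 0 calls among unchanged genes. For a step between doses the shares were 28%, 88%, 100% and 100%, with 5 calls among unchanged genes. A list changed by 0.5 was called and 0 of 29 unchanged lists were. Counts of different genes were drawn independently of each other. The simulation therefore could not show false list calls that come from correlation between genes. Libraries were drawn independently as well. False gene calls that come from deviations shared between libraries, such as paired DMSO libraries, could not show either. Simulated curves with a top of 2 and an EC50 of 10 nM gave a median fitted value of 10.2 nM.

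Alternatives fixed before the data were examined were RLE size factors, library totals, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, voom of limma, a replicate block, other uses of the DMSO libraries, fits of only the libraries compared, leaving out each library, and for EC50 another slope, prior count or dose range. A covariate, leaving out 3 libraries that stand apart (replicate 2 of 0.1 nM and replicate 1 of 1 and of 1000 nM) and a DMSO comparison blocked by number were added after seeing the data. Same-numbered DMSO libraries of both chips deviated together, with correlations of 0.123 to 0.271 across genes, so the numbers pair the DMSO libraries. Means and SDs of DMSO take the mean of each pair as 1 value, while the model counts the 6 libraries as separate. Regroupings of the libraries were first looked at in a smaller draw, and the number was then set at 100 of 840 possible splits per dose.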

Results

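Expression of 20802 genes was measured in LoVo colorectal cancer cells treated for 24 hours with a MEK inhibitor at 10 doses from 0.03 to 1000 nM, or with DMSO. Each dose had 3 libraries and DMSO had 6, of which 3 came from each of a pair of sequencing chips. Same-numbered DMSO libraries of both chips deviated together, so DMSO values are given over 3 pair means. Total counts per library lay between 2972186 and 4751839. In all, 12102 genes passed the filter. The series asks how the inhibitor changed expression relative to DMSO across the doses. Values are means of normalised counts scaled to library size (CPM) with the SD, or log2 fold changes with their standard error, and calls are those of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment against the DMSO libraries of either chip.

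At 1000 nM the genes that ERK signalling is known to switch on fell together. DUSP6, a phosphatase that inactivates ERK, went from 64.2 ± 3.27 CPM (SD, n = 3 pairs) in DMSO to 1.89 ± 0.468 CPM (n = 3), a log2 fold change of -5.06 (SE 0.196). ETV4 and ETV5, transcription factors downstream of ERK, changed by -3.86 (SE 0.201) and -4.13 (SE 0.247), DUSP4 by -2.37 (SE 0.124) and the receptor EPHA2 by -2.29 (SE 0.127). The Sprouty gene SPRY2, an inhibitor of the pathway, changed by -1.58 (SE 0.139). SPRY4 had 57 counts in the DMSO libraries and 0 in the 3 libraries at 1000 nM, at least 10.1-fold lower against a floor of 3 counts over the group. PHLDA1 and the cell cycle gene CCND1 fell by less, -0.54 (SE 0.095) and -0.62 (SE 0.099), and EPHA4 did not pass the test at 0.07 (SE 0.339). Of the 10 members of this MAPK activity list, 9 fell, also 9 when adjusted over the list alone, and the list median was -2.33, with and without SPRY4 at its bound (camera, adjusted p = 2.93e-09). The sign of EPHA4 turned, without a call, with the DMSO libraries of chip 2 alone, where it was -0.032, and without replicate 1 of chip 1 (-0.018), replicate 1 of chip 2 (-0.10) or replicate 3 of 1000 nM (-0.27).

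Other genes known to respond to ERK moved the same way. Of 11 tested members of that list, 7 fell and 1 rose, also 7 and 1 when adjusted over the list alone, with a median of -1.04 (camera, adjusted p = 0.000171). FOSL1, a subunit of the AP-1 transcription factor, changed by -2.86 (SE 0.159), the pathway inhibitors SPRED1 and SPRED2 by -1.90 (SE 0.172) and -1.68 (SE 0.144), and DUSP5 by -1.57 (SE 0.154). Among 8 immediate early genes, which respond within minutes to growth signals, 4 fell both over all genes and when adjusted over the list alone: MYC by -2.92 (SE 0.103), EGR1 by -4.17 (SE 0.245), FOS by -1.53 (SE 0.391) and KLF6 by -0.37 (SE 0.113). The median of that list was -0.38 (camera, adjusted p = 0.0232), and its call was lost with an estimated correlation (adjusted p = 0.0783) and with at least 1 CPM in 3 libraries (0.0635). KLF6 lost its call without replicate 3 of 1000 nM, with an adjusted p of 0.0918 in edgeR's quasi-likelihood test. EGFR ligands, growth factors that feed back on the cells, fell in 3 of 5 members, and in 5 of 5 when adjusted over the list alone, with a median of -2.35 (camera, adjusted p = 0.000704). HBEGF changed by -2.97 (SE 0.191), AREG by -2.67 (SE 0.169) and EREG by -2.35 (SE 0.288), while BTC was -0.55 (SE 0.207) and did not pass over all genes, but did with DMSO chip 1 alone (edgeR's quasi-likelihood test, adjusted p = 0.00562), against the mean of the DMSO groups (0.00802) and with DMSO summed over chips (0.00892). Of the pathway's kinases, MAPK3 rose by 0.91 (SE 0.108) and MAP2K1 changed by -0.31 (SE 0.095), with a call that was lost when only the libraries compared were fitted (edgeR's quasi-likelihood test, adjusted p = 0.0512) and without replicate 2 of 1000 nM (0.0619) or of DMSO chip 2 (0.122). MAP2K2 and BRAF stood at 0.11 and 0.24 and did not pass, although BRAF did against the mean of the DMSO groups (edgeR's quasi-likelihood test, adjusted p = 0.0285) and with DMSO chip 1 alone (0.0195).

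In all, 5064 of 12102 genes were called at 1000 nM, 2561 higher and 2503 lower, and 854 and 822 of them by at least 2-fold. Among the largest rises were MUC20, a membrane mucin, at 4.61 (SE 0.352), the keratin KRT14 at 4.60 (SE 0.334), the hepatic lipase LIPC at 3.95 (SE 0.196), the fatty acid transporter CD36 at 3.72 (SE 0.211), the metalloreductase STEAP4 at 3.64 (SE 0.282) and HGD, an enzyme of tyrosine breakdown, at 3.61 (SE 0.685). C20orf151 had 0 counts in the 6 DMSO libraries and 79 at 1000 nM, at least 49.7-fold higher. It also had 8 counts at 0.03 nM, 6 at 0.1 nM and 18 at 0.3 nM, doses at which no gene was called. The size of its bounds thus rests on the 0 in DMSO, which those doses did not share. UGT2A3, a glucuronosyltransferase, had 4 counts in DMSO and 59 at 1000 nM, a log2 ratio of 4.80 with a 95% counting interval of 3.37 to 6.72. The cytokine IL33 had 103 counts in DMSO and 0 at 1000 nM, at least 18.2-fold lower. LOC100287314, TNS4, MYEOV and SH3TC2 changed by -5.16 (SE 0.382), -4.73 (SE 0.309), -4.55 (SE 0.387) and -3.67 (SE 0.367), and TNS4 encodes a focal adhesion protein. TRABD2A changed by -3.59 (SE 0.379) and belongs to a set of genes that also differed between libraries of the same dose.

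**Figure D1:**
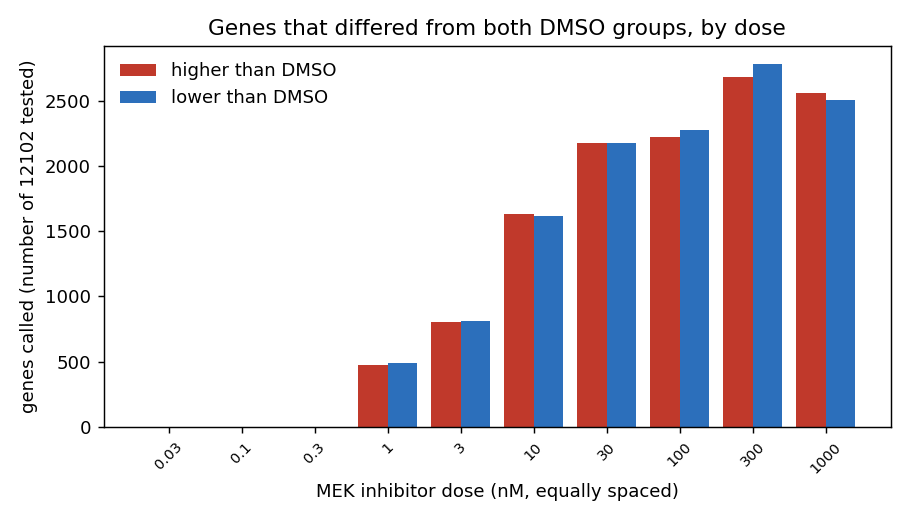
Genes called higher (red) or lower (blue) than both DMSO groups at each dose, as numbers on a linear axis from 0, with doses in nM equally spaced. No gene was called up to 0.3 nM, 965 were called at 1 nM and 5457 at 300 nM.

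Genes of cell growth and division were lower at 1000 nM. All 29 tested members of the ribosome biogenesis list fell, also 29 when adjusted over the list alone, with a median of -1.47 (camera, adjusted p = 6.11e-25). Most of these genes act in making or processing ribosomal RNA, though not all, such as SRM and ODC1. LYAR changed by -2.31 (SE 0.128), the helicase DDX21 by -1.91 (SE 0.117), GNL3 by -1.76 (SE 0.109) and RRP12 by -1.74 (SE 0.115). Of 33 G1/S genes, which prepare and carry out DNA replication, 24 fell, 25 when adjusted over the list alone, with a median of -0.53 (camera, adjusted p = 1.14e-06). The replication factors CDC45 and ORC6 changed by -1.16 (SE 0.14) and -1.14 (SE 0.142), and the helicase subunits MCM3 and MCM7 by -0.81 (SE 0.089) and -0.85 (SE 0.101). Of 30 G2/M genes, which carry out mitosis, 21 fell, 23 when adjusted over the list alone, with a median of -0.50 (camera, adjusted p = 2.23e-06). AURKB changed by -1.26 (SE 0.187), MAD2L1 by -1.02 (SE 0.11), KIF2C by -0.95 (SE 0.122) and PLK1 by -0.79 (SE 0.106). The ribosomal proteins had a median of 0.01 and a mean of -0.07, and the test pointed down without a call (camera, adjusted p = 0.984). Of 32 tested members 4 rose and 5 fell, 1 and 2 when adjusted over the list alone, among them RPL37 at -0.52 (SE 0.099) and RPS9 at -0.61 (SE 0.128). The call of RPS9 was lost with a covariate chosen after seeing the data (edgeR's quasi-likelihood test, adjusted p = 0.0557).

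Metabolic gene lists moved in both directions. Of 19 genes of the amino acid stress response, 16 fell and 1 rose, also 16 and 1 when adjusted over the list alone, with a median of -1.73 (camera, adjusted p = 3.84e-15). PSAT1 of serine synthesis went from 797 ± 24 CPM (SD, n = 3 pairs) to 115 ± 18 CPM (n = 3), a change of -2.79 (SE 0.106). The cystine transporter SLC7A11 changed by -2.55 (SE 0.116), the asparagine synthetase ASNS by -2.48 (SE 0.109) and the mitochondrial folate enzyme MTHFD2 by -2.21 (SE 0.085). Cholesterol synthesis genes rose in 14 of 21 members, also 14 when adjusted over the list alone, with a median of 0.66 (camera, adjusted p = 8.43e-05). HMGCS1, an enzyme of the pathway, rose by 1.74 (SE 0.132), INSIG1 by 1.57 (SE 0.128) and FDFT1 by 1.11 (SE 0.102). Lysosome and autophagy genes rose in 15 of 24 members, also 15 when adjusted over the list alone, with a median of 0.50 (camera, adjusted p = 0.000148). The sialidase NEU1 rose by 1.47 (SE 0.109), the autophagy receptor SQSTM1 by 1.14 (SE 0.096), PSAP by 0.93 (SE 0.088) and the protease CTSD by 0.79 (SE 0.096). Interferon response genes rose in 17 of 21 members, 18 when adjusted over the list alone, with a median of 1.27 (camera, adjusted p = 2.93e-09). IFI6 rose by 2.40 (SE 0.227), the antiviral IFIT1 by 1.85 (SE 0.228), MX1 by 1.32 (SE 0.12) and ISG15 by 1.27 (SE 0.13).

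Markers of secretory gut epithelium fell in 3 of 5 tested members and rose in 1, also 3 and 1 when adjusted over the list alone, with a median of -1.36 (camera, adjusted p = 0.00953). The gel-forming mucin MUC2 changed by -3.58 (SE 0.127), REG4 by -2.54 (SE 0.112) and SPINK4 by -1.36 (SE 0.326), while AGR2 rose by 0.53 (SE 0.096). This call was lost with no filter on low counts (adjusted p = 0.131) and with at least 1 CPM in 3 libraries (adjusted p = 0.0687). The 3 tested markers of fibroblasts, connective tissue cells, all rose, also 3 when adjusted over the list alone, with a median of 3.71 (camera, adjusted p = 0.00325). The collagen genes COL3A1 and COL1A1 rose from 1.24 ± 0.309 and 1.95 ± 0.484 CPM (SD, n = 3 pairs) to 16.8 ± 3.82 and 12.9 ± 1.76 CPM (n = 3), and the matrix proteoglycan LUM to 10.9 ± 2.73 CPM. The other 6 markers of that list, COL1A2, DCN, PDGFRA, THY1, FAP and POSTN, had 12 counts together at 1000 nM against 451 of those 3 genes. These were 6 each of DCN and PDGFRA, which had 0 and 1 in the 6 DMSO libraries. With an estimated correlation, 12 of the 13 lists called at 1000 nM were called and only the immediate early list was not.

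**Figure D2:**
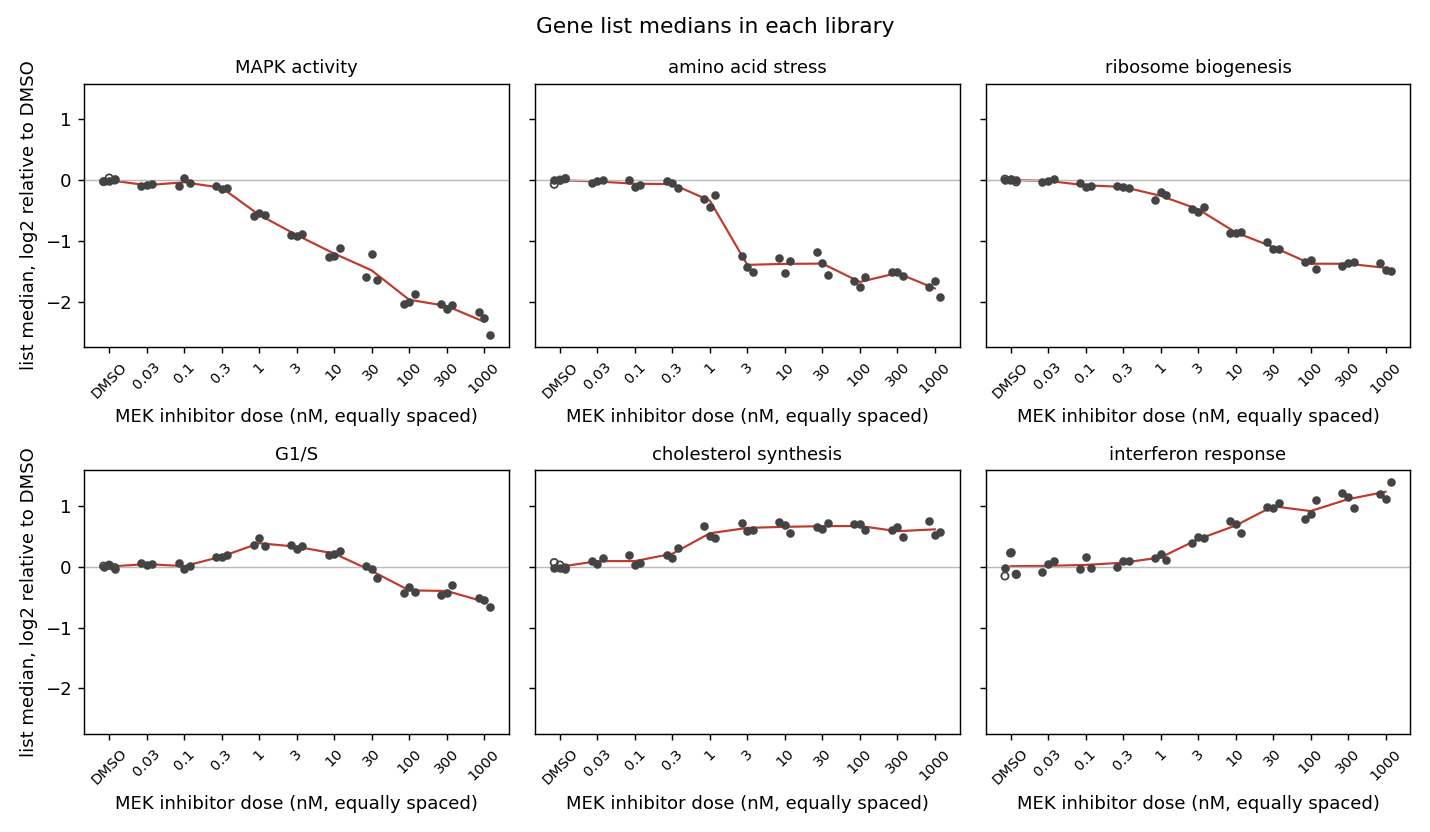
Median log2 value of 6 gene lists relative to DMSO in each library (points) and the mean of each group (line), against dose in nM, equally spaced; open circles are the DMSO libraries of chip 2. The MAPK activity median was -2.33 at 1000 nM in the model, and the G1/S median was 0.40 at 1 nM and -0.53 at 1000 nM.

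The other 17 lists tested at 1000 nM were not called. In the BCL2 family 4 rose and 4 fell of 12, with the same numbers when adjusted over the list alone, and the pro-apoptotic members BMF and BCL2L11 rose by 3.36 (SE 0.173) and 2.05 (SE 0.144), with a list median of 0.08 (camera, adjusted p = 0.728). Of 12 MHC class I genes 7 rose and 1 fell, also when adjusted over the list alone, including TAP1 at 0.92 (SE 0.122) and PSMB9 at 0.87 (SE 0.128), with a median of 0.58 (camera, adjusted p = 0.0647). The list was called with DMSO chip 1 alone (camera, adjusted p = 0.0475) and without replicate 1 of 1000 nM (0.016). In settings added after seeing the data it was also called without 3 libraries that stand apart (replicate 2 of 0.1 nM, replicate 1 of 1 nM and replicate 1 of 1000 nM, 0.00843) and with the covariate described below (camera, adjusted p = 0.00359). Among absorptive enterocyte markers 4 rose and 3 fell of 10, also over the list alone, with CEACAM6 at -2.85 (SE 0.162) and CEACAM5 at -1.54 (SE 0.107); the median was 0.07 and the mean 0.31 while the test pointed down (camera, adjusted p = 0.984). Glycolysis and hypoxia genes rose in 5 and fell in 9 of 21, with NDRG1 at 2.16 (SE 0.12) and HK2 at -1.98 (SE 0.119) and a median of -0.30 (camera, adjusted p = 0.246). For p53 targets the numbers were 6 and 5 of 20, with BTG2 at 0.87 (SE 0.127), PLK3 at -1.87 (SE 0.298), a median of 0.02 and a mean of -0.02 (camera, adjusted p = 0.993), where the test had different signs against the DMSO groups. Epithelial genes rose in 7 and fell in 5 of 14, with CDH1 at 0.79 (SE 0.086), CLDN4 at 0.85 (SE 0.1) and a median of 0.27 (camera, adjusted p = 0.463). For these 3 lists the numbers adjusted over the list alone were the same.

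Smaller lists without a call included members that passed alone. ERBB3 rose by 0.53 (SE 0.093) and FGFR4 changed by -0.65 (SE 0.13) among 10 receptor kinases, of which 2 rose and 2 fell, with a median of 0.08 (camera, adjusted p = 0.993). TNFRSF19 rose by 1.61 (SE 0.216) and ZNRF3 changed by -1.43 (SE 0.197) among 15 WNT and crypt stem genes, of which 2 rose and 2 fell, with a median of 0.00, a mean of -0.04 and a test that pointed down (camera, adjusted p = 0.993). XBP1 and HERPUD1 changed by -1.13 (SE 0.122) and -0.96 (SE 0.116) in the unfolded protein response, where 3 rose and 6 fell of 16 with a median of -0.09 (camera, adjusted p = 0.463). In heat shock genes 5 rose and 2 fell of 16, with HSPA1B at 1.49 (SE 0.165), HSPD1 at -0.64 (SE 0.101) and a median of 0.10 (camera, adjusted p = 0.537). With the covariate that median was 0.43 with a call (camera, adjusted p = 0.0376). Of 9 NF-kB targets 2 rose, 1 when adjusted over the list alone, NFKBIA by 1.06 (SE 0.129) and BIRC3 by 1.06 (SE 0.412), with a median of 0.22 (camera, adjusted p = 0.525). BIRC3 was not called by DESeq2 (adjusted p = 0.0576), by voom (0.0537), with the stricter filter (0.0512) or without any of 5 single libraries, where the adjusted p of edgeR's quasi-likelihood test reached 0.156. In the lists of receptor kinases, WNT, unfolded protein response and heat shock genes the numbers adjusted over the list alone were the same.

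Of 14 YAP/TEAD targets 2 rose and 3 fell, also over the list alone, with ARHGEF17 at 1.10 (SE 0.131) and F3 at -0.62 (SE 0.132), and the median was 0.07 and the mean -0.16 while the test pointed up (camera, adjusted p = 0.931). Of 5 AhR targets 2 rose, also over the list alone, ALDH3A1 by 1.64 (SE 0.219) and CYP1A1 by 1.86 (SE 0.416), with a median of 0.25 (camera, adjusted p = 0.334). Of 9 NRF2 targets 2 rose and 3 fell, 3 and 4 when adjusted over the list alone, with HMOX1 at 1.83 (SE 0.195), a median of -0.10 and a mean of 0.02, and the test pointed down (camera, adjusted p = 0.993). Among 4 mesenchymal genes only VIM passed, at 0.99 (SE 0.15), also over the list alone, while SNAI1 stood at -0.81 (SE 0.316); the list median was -0.13 and its test pointed up (camera, adjusted p = 0.862). Of 10 reference genes 1 rose and 3 fell, also over the list alone, with ACTB at 0.82 (SE 0.117), a median of 0.03 and a mean of -0.20, and the test pointed down (camera, adjusted p = 0.984). GAPDH stood at -0.12 (SE 0.122) and did not pass, but was called without replicate 1 of 1000 nM (edgeR's quasi-likelihood test, adjusted p = 0.0269) and without the 3 libraries that stand apart (0.000503). SNAI1 was called against the mean of the DMSO groups (edgeR's quasi-likelihood test, adjusted p = 0.00965), with DMSO chip 1 alone (0.00629), with DMSO summed over chips (0.0104) and without replicate 1 of DMSO chip 2 (0.0254).

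Across the doses, the number of called genes was 0 at 0.03, 0.1 and 0.3 nM in edgeR's quasi-likelihood test, with 42, 299 and 330 genes at an unadjusted p below 0.05, and was 0 at these doses in DESeq2 and voom as well. It was 965 at 1 nM, 1615 at 3 nM, 3249 at 10 nM, 4352 at 30 nM, 4499 at 100 nM, 5457 at 300 nM and 5064 at 1000 nM. At 0.1 nM the ribosome biogenesis list had a median of -0.11 with a call (camera, adjusted p = 0.0377). This call was lost with an estimated correlation (0.297) and without the 3 libraries that stand apart (0.18) and kept with the covariate (0.0108). At 0.3 nM, where no gene was called, several lists moved by small amounts. The cholesterol synthesis list had a median of 0.22 and the G1/S list of 0.18, both called by camera and also with an estimated correlation, as were the other ERK-responsive list at -0.18 and ribosome biogenesis at -0.11. The MAPK activity list at -0.15 and the EGFR ligands at -0.44 were called at the preset correlation and not with an estimated one, where the adjusted p were 0.0733 and 0.0517. When only the libraries compared were fitted, 125 genes were called at 0.3 nM.

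At 1 nM, the lowest dose with calls, 478 genes were higher and 487 lower. PLA2G2A, a secreted phospholipase, rose by 1.68 (SE 0.126), and CACNG4, NPTX2, OXER1 and RASSF4 by 1.84 (SE 0.404), 1.59 (SE 0.282), 1.57 (SE 0.396) and 1.46 (SE 0.394). WDR45, the RNA-binding protein gene HNRNPA3, the transcription factor CEBPB, the histone gene HIST1H2BF and IL33 changed by -3.43 (SE 0.734), -3.30 (SE 0.76), -2.53 (SE 0.407), -2.36 (SE 0.518) and -2.35 (SE 0.532). HNRNPA3 and HIST1H2BF led a set of genes that differed between libraries of the same dose, and HNRNPA3 ranged from -5.17 to -0.58 between the 3 libraries at 1000 nM, whose MAPK activity medians lay between -2.55 and -2.17. With that difference as a covariate, chosen after seeing the data, 456 genes were called at 1 nM, and 7 of the genes above were not among them. The score behind the covariate also differed between doses, without a steady order. It ran from -0.15 to 0.26 in DMSO, -1.57 to -0.97 at 1 nM, -1.12 to -0.33 at 3 nM, -1.73 to -0.63 at 100 nM, -2.71 to -1.84 at 300 nM and -2.73 to -0.25 at 1000 nM, so the covariate also takes up differences between doses. Of the 7 genes, HNRNPA3 stood at -0.70, HIST1H2BF at -0.49, CEBPB at -1.11 and WDR45 at -1.44. HNRNPA3 and HIST1H2BF are among the 20 genes that make up the score, so their smaller fold follows from how it was built. IL33 at -1.77, OXER1 at 1.27 and RASSF4 at 1.15 kept more of their fold. Leaving out single libraries also ended the calls of HNRNPA3 (without replicate 2 of 1 nM), OXER1 (without replicate 2 of 1 nM, or replicate 2 or 3 of DMSO chip 1) and RASSF4 (without replicate 1 or 2 of 1 nM, replicate 2 of DMSO chip 1 or replicate 3 of DMSO chip 2), at adjusted p of 0.0503 to 0.114 in edgeR's quasi-likelihood test. Cholesterol synthesis genes rose in 14 of 21 members, 16 when adjusted over the list alone, with a median of 0.56, and G1/S genes rose in 14 of 33, 18 when adjusted over the list alone, with 1 lower, with a median of 0.40 (camera, adjusted p = 8.47e-14 and 1.39e-08). MAPK activity genes fell in 5 of 10, 6 when adjusted over the list alone, with a median of -0.53, and amino acid stress genes in 9 of 19, 12 over the list alone, with a median of -0.33. Heat shock genes rose in 5 of 16 members, 7 when adjusted over the list alone, with a median of 0.30 (camera, adjusted p = 0.00237) and adjusted p = 0.0678 with an estimated correlation.

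**Figure D3:**
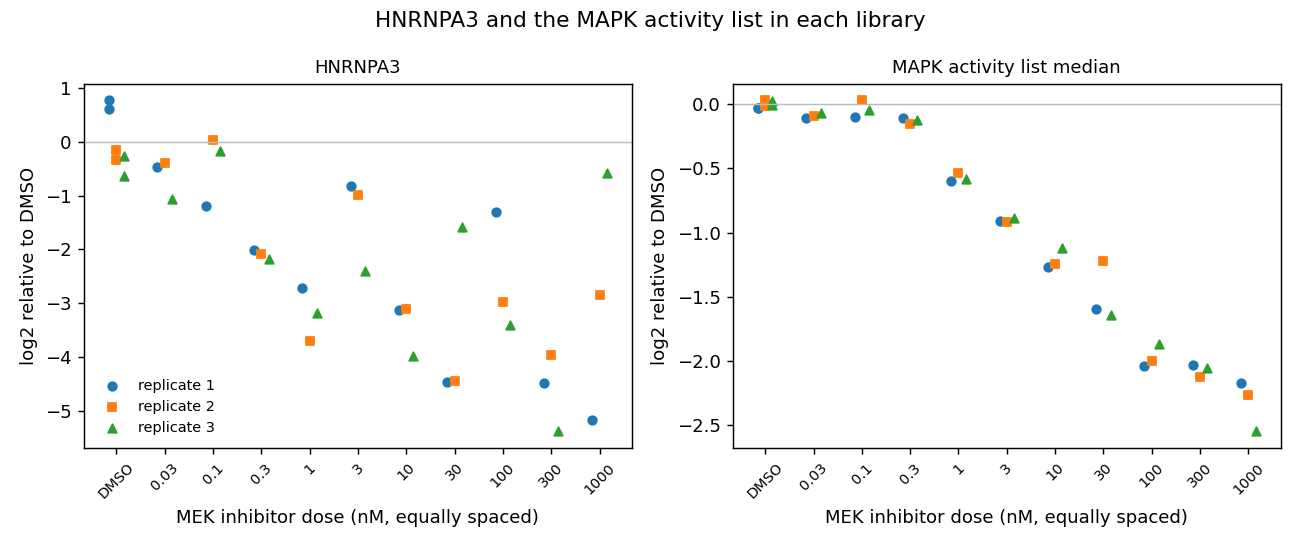
HNRNPA3 and the median of the MAPK activity list in each library, as log2 relative to DMSO, against dose in nM, equally spaced; marker shapes are replicate numbers. At 1000 nM HNRNPA3 spans -5.17 to -0.58 and the list median -2.55 to -2.17.

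Among called genes with a mean of at least 5 CPM in the higher group and no overlap with DMSO libraries, the largest changes at the middle doses were MT3, a metallothionein, at 2.61 (SE 0.417) and EGR1 at -3.04 (SE 0.204) at 3 nM, and KRT14 at 3.02 (SE 0.395) and TNS4 at -3.60 (SE 0.269) at 10 nM. C20orf151, below that limit at 10 nM, was at least 23.4-fold higher there. At 30 nM IL33 was at least 18.1-fold lower and C20orf151 at least 35.4-fold higher than DMSO, and at 100 nM these bounds were 18.9 and 48.4. At 300 nM C20orf151 was at least 46.3-fold higher and MYEOV changed by -5.10 (SE 0.411). The G1/S list, higher than DMSO at 1 and 3 nM with medians of 0.40 and 0.32, was lower at 100, 300 and 1000 nM with medians of -0.42, -0.38 and -0.53. At 10 nM its median of 0.25 was called at the preset correlation only, with adjusted p = 0.15 with an estimated correlation. With the covariate it was 0.08 without a call (camera, adjusted p = 0.343).

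**Figure D4:**
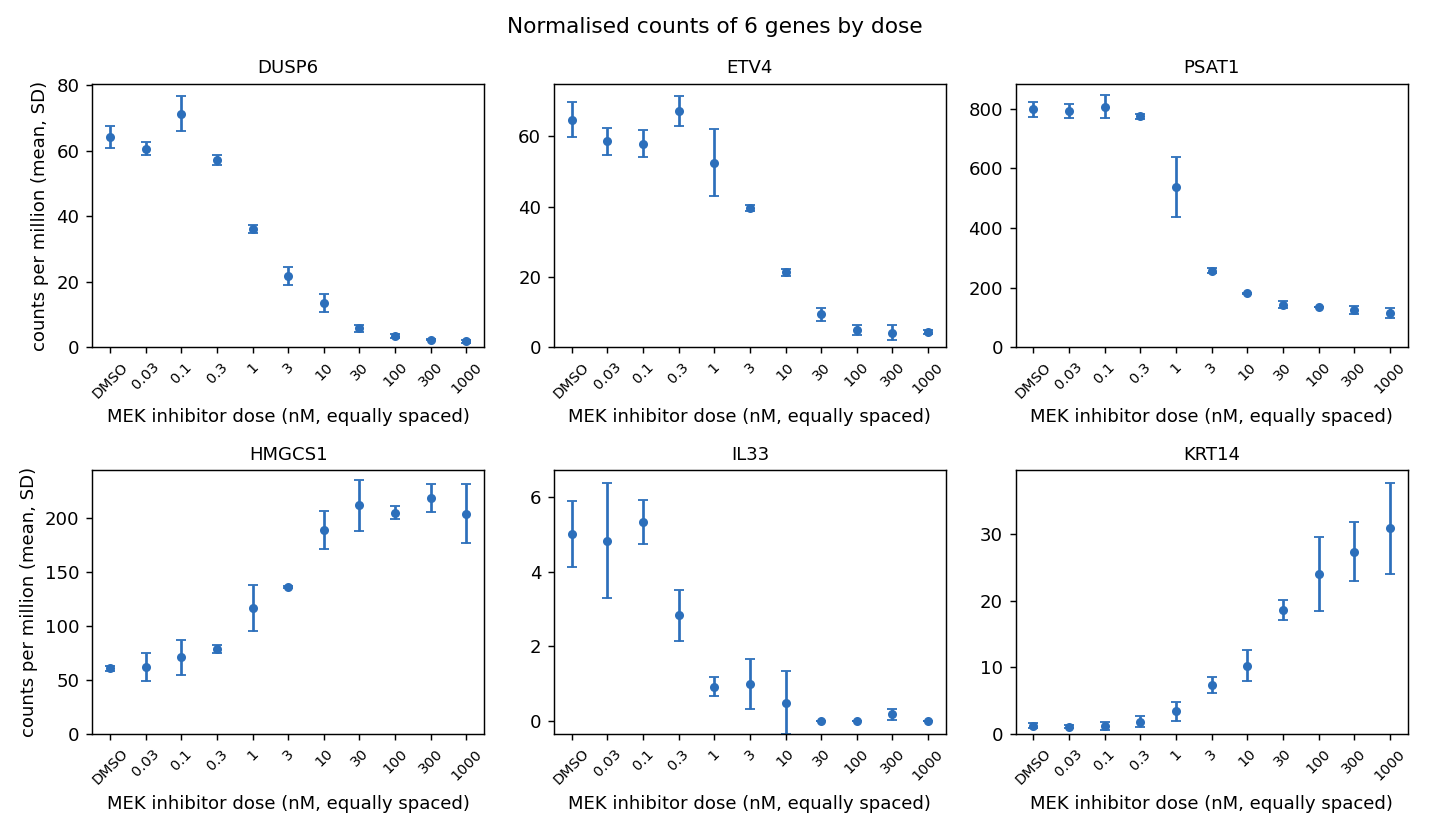
Normalised counts scaled to library size (CPM; mean, bars 1 SD; 3 pairs of DMSO libraries, 3 libraries per dose) of DUSP6, ETV4, PSAT1, HMGCS1, IL33 and KRT14 against dose in nM, equally spaced, on linear axes of different scale. DUSP6 went from 64.2 CPM in DMSO to 1.89 CPM at 1000 nM, and PSAT1 from 797 to 115 CPM.

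Steps between doses a factor of 10 apart were tested directly. A step takes a single test, while a dose had to pass against the DMSO groups of both chips. Counts for steps are therefore not comparable with counts for doses against DMSO. The labels do not name the chip of treated libraries. In the order of the samples, 0.03 to 3 nM follow DMSO of chip 1 and 10 to 1000 nM follow DMSO of chip 2. If the chips kept that order, which no label states, the step from 1 to 10 nM crosses them. Where the doses of a step ran on different chips, chip and dose cannot be told apart. From 0.1 to 1 nM 1820 genes were called, 988 higher and 832 lower, with rises of the glycolytic enzyme gene ALDOC at 1.79 (SE 0.352), NPTX2 at 1.59 (SE 0.263) and PLA2G2A at 1.44 (SE 0.119), and falls of HNRNPA3 at -2.86 (SE 0.762), HIST1H2BF at -2.02 (SE 0.517) and the chemokine CXCL1 at -1.95 (SE 0.349). The balance turned to 806 higher and 995 lower with library totals, 924 and 1101 with no filter and 805 and 901 with DMSO summed over chips. When only the libraries compared were fitted, 221 were higher and 336 lower. The count was 934 with the covariate, 922 without the 3 libraries that stand apart and 887 without replicate 2 of 0.1 nM, and the call of HNRNPA3 was lost without it and without replicate 2 of 1 nM (edgeR's quasi-likelihood test, adjusted p = 0.053 and 0.0575), while that of HIST1H2BF was lost with the covariate (0.208). HIST1H2BF is among the genes that make up the covariate's score, so that loss follows from how the score was built. From 1 to 10 nM 1866 genes were called, 854 higher and 1012 lower, or 1095 and 849 with library totals in place of TMM. When only the libraries compared were fitted the count was 901. LOC154761, FAM83E and GAL3ST2 rose by 2.18 (SE 0.252), 2.11 (SE 0.318) and 1.99 (SE 0.324), and TNS4, the chemokine receptor CXCR4 and CHAC1, a glutathione-degrading enzyme of the amino acid stress list, changed by -2.48 (SE 0.298), -2.35 (SE 0.309) and -2.02 (SE 0.125). Ribosome biogenesis genes fell in 25 of 29 members, 26 when adjusted over the list alone, with a median of -0.56 (camera, adjusted p = 6.16e-22).

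From 10 to 100 nM 622 genes were called, 216 higher and 406 lower, and 1030 when only the libraries compared were fitted. The selenoprotein gene SEPP1, the bicarbonate transporter SLC4A4 and MYL2 rose by 1.44 (SE 0.169), 1.34 (SE 0.218) and 1.29 (SE 0.365), and ETV4, DUSP6 and ETV5 changed by -2.08 (SE 0.222), -1.92 (SE 0.213) and -1.81 (SE 0.278). G1/S genes fell in 20 of 33 members, 27 when adjusted over the list alone, with a median of -0.58 (camera, adjusted p = 2.71e-29). The count was 339, 343, 357 and 395 without replicate 1 or 2 of 10 nM and replicate 1 or 3 of 100 nM, and MYL2 lost its call without replicate 1 or 2 of either dose. From 100 to 1000 nM 1 gene was called, MALL, a membrane protein gene, at -0.79 (SE 0.126), with 815 at an unadjusted p below 0.05 in edgeR's quasi-likelihood test. It was not called when only the libraries compared were fitted (adjusted p = 0.198), and 3 genes were called without any single library of 1000 nM.

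The DMSO libraries of both chips, which had the same treatment, differed in 0 genes in edgeR's quasi-likelihood test, with 308 at an unadjusted p below 0.05, in 0 genes with voom and in 2 with DESeq2. The transcription factor gene KLF15, the chemokine gene CXCL2 and C6orf162 stood at -0.79 (SE 0.275), -0.77 (SE 0.361) and -0.76 (SE 0.262) in chip 2 relative to chip 1, and SNRNP27, WDR85 and DPY19L4 at 0.84 (SE 0.415), 0.88 (SE 0.321) and 0.90 (SE 0.46), none with a call. With the 6 libraries paired by replicate number as a block, 177 genes were called, among them DPY19L4 (edgeR's quasi-likelihood test, adjusted p = 0.0319), a comparison added after seeing the data.

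Genes changed at different doses along the curve. For the 7 fitted members of the MAPK activity list the median EC50 was 9.60 nM. DUSP6 had an EC50 of 9.60 nM (95% interval 7.62 to 12.1) and MYC of 10.2 nM (8.56 to 12.2). The curves were fitted to log2 values, so an EC50 marks the midpoint of the log2 change and not of the RNA level. DUSP6 already stood at -0.83 at 1 nM and -1.56 at 3 nM. Cholesterol synthesis genes had a median of 0.921 nM over 4 genes, with HMGCS1 at 1.15 nM (0.801 to 1.66), EGFR ligands 1.47 nM over 3 and amino acid stress genes 1.94 nM over 13, with PSAT1 at 2.55 nM (2.07 to 3.14). Ribosome biogenesis genes had a median of 6.10 nM over 24 genes and interferon response genes of 5.63 nM over 15. Over all 1676 fitted genes the median was 3.94 nM, and 931 were well fitted. The lowest values among these were PCYT2 at 0.332 nM, RPS6KA5 at 0.343 nM and OXER1 at 0.409 nM, and the highest were the apoptosis inhibitor BCL2 at 82.9 nM, FAM3D at 187 nM and MALL at 204 nM (122 to 341). FAM3D was called higher than DMSO at 3 and 10 nM, at 0.33 and 0.37, and lower from 100 nM, so its EC50 does not describe a single response. Differences between lists in EC50 were not tested. The midpoint also depends on how far a gene's log2 value moves in all, so these values do not rank lists by sensitivity. Taken per library, the list medians at 1 nM were -0.575 for MAPK activity and 0.547 for cholesterol synthesis.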

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

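The tests of explanations below were chosen after the results were seen, and the counts over other groupings of the libraries were planned before the data were examined.

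G1/S genes stood above DMSO at 1 nM and below it at 1000 nM, and their list median changed by -0.20 from 1 to 10 nM, by -0.58 from 10 to 100 nM and by -0.23 from 100 to 1000 nM. The first of these steps had adjusted p = 0.0759 with an estimated correlation in camera, and the other 2 kept their calls. A difference between the chips would need the list to differ between the DMSO libraries, and there the medians differed by 0.011 (SE 0.025, which does not use the pairing of same-numbered DMSO libraries). The difference between libraries of the same dose described for HNRNPA3 would need the rise to vanish once it is modelled, and with that covariate the median at 1 nM was 0.273 (camera, adjusted p = 4e-07). A candidate explanation that stays open is a response to the inhibitor that reverses with dose, a hypothesis found and tested on the same libraries.

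The fibroblast markers COL1A1, COL3A1 and LUM were higher at 1000 nM. RNA from fibroblasts would bring the other markers of that cell type, and COL1A2, DCN, PDGFRA, THY1, FAP and POSTN together had 2.66 counts per 100 counts of those 3 genes, with an upper 95% bound of 4.69 from counting alone. This does not exclude it, since amplicons differ in yield, COL1A2 and FAP had 0 counts in every library, and DCN and PDGFRA had 6 counts each at 1000 nM against 0 and 1 in DMSO. Of other genes abundant in fibroblasts, SPARC had 0 counts at 1000 nM but only 3 in all libraries, and MMP2 had 0 in every library. With so few counts anywhere, neither gene could show fibroblast RNA. In the mesenchymal list that holds both, VIM was called higher at 1000 nM, at 0.99, and SNAI1 stood at -0.81 without a call. With the covariate for differences within doses the list median was 3.50 (camera, adjusted p = 0.00254). Taken per library, the list median was 0.00 ± 0.62 at 0.3 nM and 1.31 ± 0.29 at 1 nM (log2 relative to DMSO, SD, n = 3). It was 2.68 ± 0.30 at 30 nM and 3.37 ± 0.10 at 1000 nM. For these 3 genes, such a rise along the doses argues against fibroblast RNA that reached libraries without regard to dose. Fibroblast RNA that increased with dose and a response of the LoVo cells themselves to the inhibitor both stay open.

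HNRNPA3 and histone genes such as HIST1H2BC and HIST1H2BF differed between libraries of one dose, along a component that held 22.4% of the variance within groups over 7764 genes. All correlations in this paragraph use deviations of the libraries from their group means. They describe differences within groups and not those between doses. Its score did not follow the total count, with Pearson r = -0.055 (95% interval -0.441 to 0.348, permutation p = 0.796, Spearman rho = -0.039 with permutation p = 0.855, r = 0.099 without the 2 farthest libraries), and the 1000 nM library nearest DMSO on it, replicate 3, had a MAPK activity median of -2.55, which speaks against a wrong dose label. Genomic DNA, read from olfactory receptor genes, stays open: r = 0.49 (95% interval 0.118 to 0.742, permutation p = 0.255, rho = 0.267 with permutation p = 0.221), and 0.288 without the 2 farthest libraries. The olfactory receptor CPM of the 3 libraries at 1000 nM were 54.8, 139 and 132, against 62.1 to 69.7 in DMSO. Within groups, the score's r with the MAPK activity median was -0.647 (permutation p = 0.0551, rho = -0.479 with permutation p = 0.0302), and -0.568 without the 2 farthest libraries. Adjusted by Benjamini-Hochberg over these 3 relations, the permutation p of r were 0.796, 0.383 and 0.165 and those of rho 0.855, 0.332 and 0.0906, and no biological explanation was tested.

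In all, 36 genes were called in opposite directions at 1 and 1000 nM with edgeR, 25 of them higher at 1 nM, among which 9 are G1/S members, and 11 lower. Independent lists would have 98.9 and 103 such genes. MCM3 went from 0.51 to -0.81, E2F1 from 0.66 to -0.43 and LAMB3 from -0.36 to 0.68. With the covariate 8 of the 36 genes were called in opposite directions. Both doses shared 327 rises and 364 falls, where independent lists would share 101 and 101. Simulated unchanged groups had 0 calls at either dose, so their shared number of 0 was fixed and says nothing. With the DMSO chips divided between the doses the shared calls were 523 and 557 (202 and 194 for independent lists) and the opposite ones 54 and 25 (195 and 201). With the chips exchanged they were 546 and 569 (227 and 219) and 84 and 38 (220 and 227). The same DMSO libraries serve both doses and same-numbered ones of the chips deviate together, so independent lists are no measure of chance here, and neither the excess of shared calls nor the lack of opposite ones is read as an effect.

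Groupings of 9 libraries into 3 groups of 3 were fitted alone, so the real values differ from those of the model of all libraries. At 0.03 and 0.1 nM the real grouping called 0 genes with edgeR, and the highest other called 10 and 1. All 100 groupings reach 0, so this says nothing about chance. Genes at an unadjusted p below 0.05 numbered 42 and 299 in the model of all libraries, and DESeq2 and voom called 0. At 0.3 nM the real grouping called 125 genes and the highest other 2. At 1, 3, 10, 30 and 100 nM the real values were 986, 2414, 4024, 4692 and 5152 and the highest others 1003, 2395, 4026, 4735 and 5173, from groupings that keep the 3 treated libraries together and regroup only DMSO. Among groupings that mix the treated libraries with DMSO, the highest was 0 at each of these 5 doses. At 300 and 1000 nM the real values were 5929 and 4716 and the highest other 0. For lists at 1000 nM the real grouping called 12 and the highest other 10. Of 100 groupings, 1 reached the real value at 0.3, 3, 300 and 1000 nM and for lists, 2 at 1, 10 and 100 nM and 4 at 30 nM. These groupings treat the 9 libraries as exchangeable, although same-numbered DMSO libraries pair. The real grouping parts all 3 pairs, and among the groupings that also part them it was reached by 1 of 43 at 0.3 nM, 2 of 49 at 1 nM, 1 of 59 at 3 nM, 2 of 52 at 10 nM, 3 of 41 at 30 nM, 2 of 48 at 100 nM, 1 of 37 at 300 nM and 1 of 46 at 1000 nM, for genes and for lists. Over all 100 groupings the share that reached the real value was under 0.05 at these doses and for lists. Among those that part the pairs the share stayed under 0.05 except at 30 nM, and the others that reached the real value at 1, 10, 30 and 100 nM regroup only DMSO libraries. Groupings that mix treated with DMSO libraries raise the spread within groups, so their few gene calls are no measure of chance. At 1000 nM no drawn grouping other than the real one kept the 3 treated libraries together. These shares therefore do not exclude chance.

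For steps and chips only 10 splits of 6 libraries exist, too few for a share under 0.05. The real and highest other values were 557 and 0 from 0.1 to 1 nM, 901 and 0 from 1 to 10 nM, 1030 and 0 from 10 to 100 nM, and 0 and 0 from 100 to 1000 nM. Between the chips they were 2 and 30, and the split with 30 set replicates 1 and 2 of chip 1 and replicate 1 of chip 2 against the rest, a structure of the samples that does not follow the chips. Since same-numbered DMSO libraries pair, the value blocked by number, 177 genes, stands beside it, and of the 4 splits that part all 3 pairs the 3 others called 0. The real grouping or more was reached by 1 split in each of the first 3 steps, by 10 in the last and by 2 for the chips.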

How the results depend on the processing

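The covariate, the omission of 3 libraries and the DMSO comparison blocked by number were chosen after the data were seen; all other settings were planned. Except where another reason is named, the cause was not tested.

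With no filter on low counts 1 gene was called at 0.03 nM, 4 at 0.1 nM, 40 at 0.3 nM, 5 from 100 to 1000 nM and 2 between the chips. Against the mean of the DMSO groups, which asks for 1 test in place of both, the counts were 1 at 0.03 nM, 4 at 0.3 nM, 2537 at 1 nM, 3137 at 3 nM and 4964 at 10 nM. With DMSO chip 1 alone 1652 genes were called at 1 nM, and with chip 2 alone 1 at 0.03 nM, 3 at 0.3 nM and 1789 at 1 nM. With the chip read from the values 1652 were called at 1 nM and the MAPK activity EC50 was 5.94 nM, but no chip was read at 0.1, 100 and 1000 nM and the reading failed: DMSO libraries left out of it stood at -0.049 to 0 for chip 2 and -0.101 to -0.056 for chip 1, on the same side. These values bear on nothing. With DMSO summed over chips there were 1 at 0.3 nM, 1824 at 1 nM and 2525 at 3 nM. Fits of only the libraries compared called 125 at 0.3 nM, 557 from 0.1 to 1 nM, 901 from 1 to 10 nM, 1030 from 10 to 100 nM, 0 from 100 to 1000 nM and 2 between chips. Such fits have fewer residual degrees of freedom and their own filter, scaling and spread. Which of these moved the counts up or down was not tested. DESeq2 called 2 between chips. The covariate gave 456 at 1 nM, 3395 at 300 nM, 934 from 0.1 to 1 nM, 2 from 100 to 1000 nM and 1 between chips, and omitting 3 libraries gave 922 from 0.1 to 1 nM and 4 from 100 to 1000 nM. fry called 21 lists at 1000 nM. The EC50 was 11.7 nM with a free slope, 7.92 nM without 1000 nM and 8.41 nM with a prior count of 5.

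Without single libraries, which lowers the number of samples, the counts ran from 887 to 1727 from 0.1 to 1 nM, from 339 to 536 from 10 to 100 nM and from 1 to 3 from 100 to 1000 nM. Without all libraries of 1 replicate number the EC50 ran from 9.85 to 10.1 nM. The uncalled EPHA4 fold at 1000 nM turned to -0.032 with DMSO chip 2 alone, and without single libraries it ran from -0.27 to 0.24, below 0 without replicate 1 of either DMSO chip or replicate 3 of 1000 nM. At 1 nM the counts without single libraries were 645 to 988, and at 1000 nM 4421 to 4915.

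The replicate number as a block gave 938 genes at 1 nM and 5044 at 1000 nM, 1783, 1848, 612 and 1 for the steps, 0 between the chips, 13 lists and an EC50 of 9.60 nM. Correlations across genes between treated and DMSO libraries of one number were -0.128 to 0.161, at no dose all over 0.1, and 16 of 60 matched their own number best. At 0.3 nM all 6 did, with 0.034 to 0.161. With the 6 DMSO libraries alone paired in this way 177 genes were called between chips, and in the model of all libraries the block moved no count by over 1.5 times and ended no call of a named gene.

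Of 2202 alternative values of named genes 2175 kept direction and side of the threshold, 14 lost and 12 gained a call, and 1 turned without a call. Of 1392 values without single libraries these were 1365, 22, 2 and 3. Depth limits genes with few counts, where only bounds or counting intervals are given.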

Other observations

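The histone genes and the doses compared here were chosen after the results were seen, and no explanation of them was tested.

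Histone genes, which package DNA and are made mainly while DNA is copied, are in none of the fixed lists as a group. Of 56 tested, 13 fell at 1 nM, 38 at 3 nM and 50 at 1000 nM, where 2 rose, with medians of -0.20, -0.78 and -1.45. All 66 histone genes in the files, tested or not, held 2.66% ± 0.046 of all counts in DMSO chip 1 and 2.63% ± 0.045 in chip 2 (SD, n = 3 each). Their share was 2.32% ± 0.077 at 1 nM, 1.65% ± 0.034 at 3 nM and 1.06% ± 0.011 at 1000 nM. With the covariate for differences within doses 5 of the 56 tested fell at 1 nM and 50 at 1000 nM. Its score itself holds HIST1H2BC, HIST1H2BF and HIST1H3F. Reads shared between near-identical histone genes make single members uncertain.

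Between neighbouring doses, 554 genes differed from 1 to 3 nM, 203 from 3 to 10 nM and 34 from 10 to 30 nM in edgeR's quasi-likelihood test. Here too, chip and dose cannot be told apart where neighbouring doses ran on different chips. That would hold from 3 to 10 nM if the chips kept the order of the samples. From 1 to 3 nM 14 of 19 amino acid stress genes fell, with a median of -0.56, and 30 of 56 histone genes, with a median of -0.51.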
